A study of Oryza sativa with 20 samples.

How the data were processed

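RNA from stem bases of 8 day old seedlings was measured on 20 Affymetrix rice arrays, 1 per line, treatment and time. Per the labels' protocols, seedlings grew at 26 °C with 12 h of light, were moved to liquid half-strength medium at 7 days and were treated 1 day later with 10 µM dexamethasone or with ethanol at 0.5‰. Per the labels, each RNA came from 20 stem bases and was biotin-labelled. The deposited intensity values are MAS5 signals on a linear scale, made with Affymetrix Expression Console per the submitters' processing notes, with versions not given in the sources used here. In the deposited table the 2% trimmed mean of each array is 100.0, so arrays had already been scaled. No 2 arrays held identical values.

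The table holds 57381 probe sets, of which 123 are control probe sets and were left out of all tests. Gene names came from the platform annotation, updated by gene number through a RefSeq table of the assembly ASM3414082v1. Of the others 22436 were paired with 1 gene, 95 with several and 34727 with none listed; 2457 genes had a name other than a locus number. The genome build of the arrays was not given in the sources used here, so no coordinates are printed. No probe set was matched to CRL1 by name or locus. Whether any without a listed gene measures it is not known.

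Values were log2(signal + 1.7), where the offset was the 20th percentile of all signals, so fold changes of dim transcripts are understated. A probe set was tested if its signal was above its array's median on at least 3 arrays, which left 32836. Tests used limma 3.58.1 in R 4.3.3 with 8 group means, a trended empirical Bayes variance and Benjamini-Hochberg adjustment at 0.05. All 20 arrays shared 1 estimate of the spread, with 12 residual degrees of freedom. Mock-treated CRL1 lines were compared with mock-treated control lines with line as a random block, since each line gave an array at each time (correlation 0.23). Errors beside log2 changes are standard errors of that model, and errors beside signals are SDs. The test was checked on simulated arrays with 200 changed probe sets among 32836. For the CRL1 lines at 4 h it recovered 45% of changes of 1 and 78% of changes of 2 on the log2 scale, with 6 false calls. For the CRL1 lines at 8 h these were 33% and 71%, with 1 false call. All simulated arrays had the same spread for a probe set and no differences between lines. The values at 4 h and at 8 h therefore differ by the random draw alone.

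Arrays of the same line are paired by the labels, since mock and dexamethasone samples came from the same transgenic line. Deviations from group means correlated at 0.02 to 0.17 within lines of the CRL1 groups and at -0.16 to 0.05 between lines. The control lines were not covered by this check, and the arrays of the untransformed line stood apart from all others, as given below. The blocked value, with line as a fixed block and 9 residual degrees of freedom, is printed beside a result where it changed the call or moved a count by over 1.5 times.

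Gene lists were tested with camera in limma at a preset correlation of 0.01, with 1 probe set per gene (the one with the highest mean), adjusted over the 25 lists of a comparison with at least 5 measured genes. Lists had been fixed before the data were examined as loci and description patterns. The annotation gave symbols but no descriptions, so they were rewritten as symbol patterns after the files were seen and before any comparison was computed. In that step 2 lists, LOB-domain genes and class III peroxidases, were dropped for having too few named members, and the root tissue list came to hold mostly transporters of nutrients, with the nicotianamine enzyme genes NAS1, NAS2, NAS3 and NAAT1 and the Casparian strip gene CASP1. The lists of a comparison also held markers of leaf, vascular and shoot meristem tissue. Auxin transport had 4 measured genes and was not tested as a list. For the comparison of mock-treated lines the estimated-correlation test had no line block.

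Named genes followed a rule set before the data were examined. It took every measured crown root regulator, the clock genes for time, and the genes with the largest change in each direction (10 for the CRL1 lines and for the mean difference, 5 elsewhere). These had to be called, to change the same way in every line compared, and to belong to a probe set with exactly 1 named gene. For the differences between dexamethasone responses, direction was checked in the CRL1 lines only. Up to 4 members of each other list with the smallest p were tabulated, and those that carry the comparison are printed. Alternatives were no offset or one at the median signal, no filter or a stricter one at the 75th percentile, quantile normalization, only the groups compared, line as a block, array weights and leaving out each line. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.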

Results

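Transcript levels were measured in stem bases of rice seedlings that carried the crl1 (crown rootless 1) mutation in the cultivar Taichung 65. CRL1 encodes a LOB-domain transcription factor required for crown root formation, and the mutant makes few or no crown roots. In 3 independent transgenic lines, referred to here as the CRL1 lines, the intact CRL1 coding sequence was placed under a promoter that is switched on by the synthetic glucocorticoid dexamethasone. There were 2 control lines of the same mutant: control line 1 was untransformed and control line 2 carried the empty inducible vector. Each line was sampled after mock treatment and after 10 µM dexamethasone, at 4 h and at 8 h, with 1 array per line, treatment and time. This gave 3 arrays in each of the 4 CRL1 line groups, 2 arrays in each of the 4 control line groups, and 20 arrays in all. The lines are the replicates, and RNA of 20 stem bases was pooled for each array. Except in the comparison of mock-treated lines, the tests took the arrays of 1 line as independent. Their p-values and standard errors rest on the spread between lines within a group, pooled over all groups. That pooled spread includes the differences between the 2 control lines, also in tests of the CRL1 lines alone. Every array was scaled to a trimmed mean signal of 100, and the median signal of the probe sets lay between 10.1 and 15.5. The number of arrays limits the precision. Tests covered 32836 probe sets, of which those paired with exactly 1 gene represented 16517 genes. No probe set was matched to CRL1 itself, so the induction of the transgene was not checked on these arrays. Whether a tested probe set without a listed gene measures CRL1 is not known.

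The first question was which transcripts changed in the CRL1 lines within 4 h of dexamethasone. Dexamethasone raised a small set of transcripts in the CRL1 lines at that time, and QHB had the largest rise among the called genes that met the naming rule. QHB (LOC4324824), a WUSCHEL-related homeobox gene expressed in the quiescent centre of rice roots, rose by 3.27 ± 0.45 on the log2 scale (SE, 3 lines; adjusted p = 0.00244, limma). Its signal was 16.9 ± 4.74 after mock treatment and 190.0 ± 94.6 after dexamethasone (SD, n = 3). CBL4, a calcineurin B-like calcium sensor, rose by 2.77 ± 0.35 with an adjusted p of 0.000972, and HMG1 rose by 2.59 ± 0.44. The mean mock signal of HMG1, 8.27, was under the array median, and its rise was 2.81 with no offset and 1.84 with an offset at the median. GH3-8, an enzyme that conjugates auxin to amino acids, rose by 2.23 ± 0.41. CYP734A4, a cytochrome P450 that inactivates brassinosteroids, rose by 2.09 ± 0.33. The log2 change was 1.92 ± 0.29 for IMCEL2, 1.92 ± 0.32 for Roc4, a homeobox gene of the epidermis-expressed class IV family, and 1.91 ± 0.34 for the glucanase GLU8. The proline transporter gene proT rose by 1.58 ± 0.18 from a signal of 144.0 ± 10.9 to 436.0 ± 64.0, and SK3 rose by 1.5 ± 0.31. Each of these 10 genes changed in the same direction in all 3 CRL1 lines, and no named gene met the same rule for a fall. Without CRL1 line 1 the call was lost by 9 of the 10, all but proT (adjusted p of 0.155 to 0.736). Without CRL1 line 2 it was lost by all 10 (0.0534 to 0.447), and without CRL1 line 3 by GH3-8, GLU8 and SK3 (0.0559 to 0.183). HMG1 also lost it under the stricter filter (0.15) and with only the groups compared (0.0606), and SK3 with no offset, an offset at the median, no filter and quantile normalization (0.0515, 0.0523, 0.0602 and 0.0718). None of the 10 was called for the difference from the control lines' response at 4 h. That comparison called 3 probe sets, 0 of them with a named gene.

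Of the 10 measured crown root regulators, QHB rose and 9 did not pass the test, and adjusted over the list alone 1 rose. Without CRL1 lines 1 and 2 the call of QHB was lost (adjusted p = 0.213 and 0.16). WOX11, a homeobox gene that promotes crown root growth, had a log2 change of -0.91 ± 0.5, and SHR1 one of -0.27 ± 0.18. RR2, a type-A cytokinin response regulator, stood at -0.71 and passed only with line as a block (adjusted p = 0.0432 against 0.52).

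Over all probe sets, limma with Benjamini-Hochberg adjustment called 136 higher and 7 lower at 4 h, and 118 of the higher ones changed at least 2-fold. With line as a block the counts were 296 and 58. Without CRL1 line 1 the total fell to 12, without CRL1 line 2 to 14 and without CRL1 line 3 to 67, while without control line 1 or 2 it was 224 or 223. Of 25 lists tested, Aux/IAA proteins, repressors of auxin response, were lower on balance, with a median log2 change of -0.14 and an adjusted p of 0.0463, and the adjusted p = 0.796 with an estimated correlation. No member passed over all genes, whereas adjusted over the list alone 1 rose and 3 fell. In the control lines this list was lower too, with a median of -0.2 and an adjusted p of 0.0277 (adjusted p = 0.767 with an estimated correlation), and the difference between the kinds of line was not called (median -0.03, adjusted p = 0.99). Root tissue genes, mostly transporters of nutrients, were higher on balance with a median of 0.45, no member called either way and an adjusted p of 0.0463, and the adjusted p = 0.796 with an estimated correlation. With the mean over a gene's probe sets the adjusted p was 0.0631 for both lists. Without CRL1 lines 1 and 2 the adjusted p for Aux/IAA proteins was 0.135 and 0.306. For root tissue genes it was 0.056 and 0.0541 without control lines 1 and 2, and 0.315 and 0.0666 without CRL1 lines 2 and 3. Expansins and wall-remodelling enzymes passed only with line as a block, at an adjusted p of 0.0438 against 0.19 without it.

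**Figure D1:**
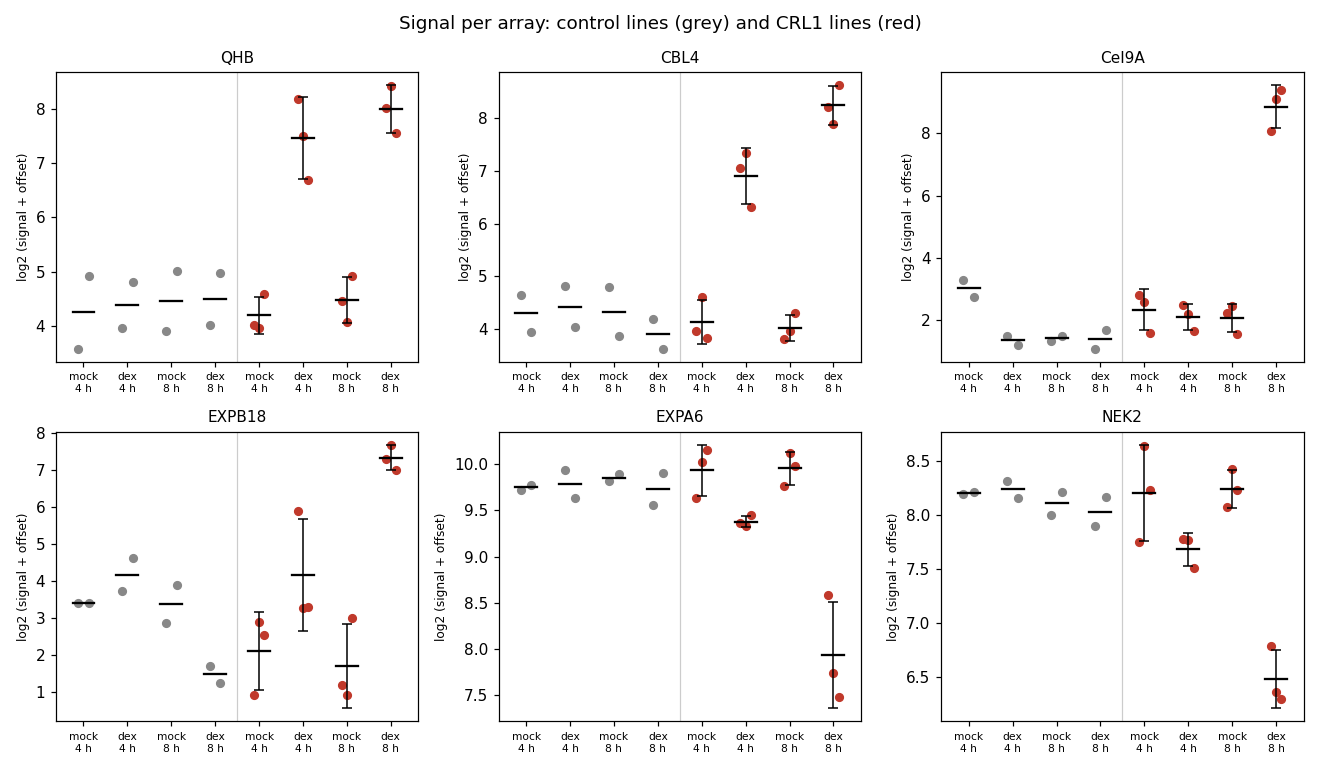
Signal of 6 named genes on each array, as log2 of the signal plus the offset, for control lines (grey points) and CRL1 lines (red points) by treatment and time. Horizontal bars are group means and error bars are the SD of the 3 CRL1 lines. QHB and CBL4 were higher after dexamethasone at both times in the CRL1 lines, while Cel9A stood at a mean signal of 2.67 at 4 h and 495.0 at 8 h.

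At 8 h both rises and falls were called in the CRL1 lines. Cel9A (LOC4324643; also GLU5), an endo-1,4-glucanase of the cell wall, rose by 6.8 ± 0.45 on the log2 scale (SE, 3 lines; adjusted p = 4.61e-07, limma). Its signal was 2.6 ± 1.28 after mock treatment, well under the array median, and 495.0 ± 206.0 after dexamethasone (SD, n = 3), and its call was lost under the stricter filter on dim probe sets (adjusted p = 0.0936). The beta-expansin EXPB18 rose by 5.62 ± 0.7 and the homeobox gene hox14 by 4.66 ± 0.82. CBL4 rose by 4.23 ± 0.35, HMG1 by 4.11 ± 0.44, CYP734A4 by 3.98 ± 0.33, GH3-8 by 3.74 ± 0.41 and QHB by 3.52 ± 0.45. C3H10 and the MADS-box gene MADS17 rose by 3.82 ± 1.04 and 3.43 ± 0.71. The mean mock signals of Cel9A, EXPB18, hox14, HMG1, C3H10 and MADS17 were under the array median, so the size of these rises depended on the offset. With no offset they were 7.62, 7.45, 4.92, 4.36, 4.58 and 3.84 in that order, and with an offset at the median 5.05, 3.62, 3.73, 3.23, 2.39 and 2.35. Without CRL1 line 2, hox14, C3H10 and MADS17 lost their calls (adjusted p = 0.075, 0.517 and 0.176), as did C3H10 without CRL1 line 1 (0.162) and MADS17 without CRL1 line 3 (0.0801). C3H10 also lost it with no offset (0.0775) and with no filter (0.0512).

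The 10 largest named falls at 8 h included those of 2 expansins. SAT5 fell by 2.59 ± 0.51 on the log2 scale, although another probe set of that gene went the other way. BHLH172 (also BU1), a positive regulator of brassinosteroid response, fell by 2.29 ± 0.49 and the calcium/proton exchanger gene CAX1a by 2.06 ± 0.56. The Aux/IAA gene IAA20 was called lower, but its mean signals after mock treatment (9.77) and dexamethasone (0.967) were both under the array median, so no size is given. The alpha-expansins EXPA6 and EXPA1 fell by 2.03 ± 0.22 and 1.78 ± 0.42. ACO1, an ethylene-forming oxidase, fell by 2.0 ± 0.39 from a signal of 3170 ± 472 to 871.0 ± 431.0. The glutaredoxin GRXC1, the homeobox gene Hox21 and the kinase gene NEK2 fell by 1.91 ± 0.39, 1.83 ± 0.25 and 1.76 ± 0.19. All 20 named genes changed in the same direction in all 3 CRL1 lines. Without CRL1 line 1, BHLH172, CAX1a and GRXC1 lost their calls (adjusted p = 0.0576, 0.0553 and 0.141). Without CRL1 line 2 these 3 (0.0866, 0.428 and 0.117), ACO1 (0.183) and EXPA1 (0.38) did, and without CRL1 line 3 CAX1a (0.334), ACO1 (0.0692) and EXPA1 (0.0935). With only the groups compared SAT5 (0.0549), IAA20 (0.0654), CAX1a (0.0507) and EXPA1 (0.0623) lost theirs, as did CAX1a with no filter (0.0504).

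Of the 10 crown root regulators, 3 rose at 8 h (QHB, hox14 and IAA23) and 2 fell (RR2 and SHR1). Adjusted over the list alone, 3 rose and 5 fell. Of the 5 calls over all genes 3, 1 and 2 were left without CRL1 lines 1, 2 and 3. IAA23 had a log2 change of 1.11 ± 0.22, RR2 of -1.26 ± 0.26 and SHR1 of -0.62 ± 0.18. WOX11, at -1.28 ± 0.5, and IAA13, at -0.6 ± 0.21, passed only with line as a block (adjusted p = 0.00185 and 0.0241 against 0.163 and 0.111). The calls of RR2 and SHR1 were lost without any 1 of the CRL1 lines (adjusted p of 0.0808 to 0.178 and of 0.164 to 0.379), and that of IAA23 without CRL1 line 2 (0.111) or 3 (0.0821). SHR1 also lost its call with an offset at the median (0.0536), no filter (0.0979), quantile normalization (0.0635) and only the groups compared (0.105). The remaining members were RR1 at 0.8 ± 0.51, SCR1 at -0.65 ± 0.23 and CKX4 at -0.65 ± 0.37. As a list these genes did not shift (adjusted p = 0.846), with a median of -0.61 and a mean of 0.5 that differed in sign.

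Aux/IAA genes moved in both directions at 8 h. Of 25 Aux/IAA genes, 2 rose and 6 fell, and adjusted over the list alone 2 rose and 10 fell. Without CRL1 lines 2 and 3 the total of 8 calls was 3 and 4, all of them falls. Besides IAA20, which was dim in both groups, IAA31 fell by 1.46 ± 0.26, IAA30 fell by 1.21 ± 0.16 and IAA15 fell by 1.07 ± 0.15, with the call of IAA31 lost without CRL1 line 2 (adjusted p = 0.117). The list test for Aux/IAA proteins gave an adjusted p of 0.0834, and 0.041 with line as a block. Of 9 GH3 and SAUR auxin response genes 3 rose: GH3-8, GH3.1 by 1.97 ± 0.31 and GH3.4 by 1.32 ± 0.36, and the count was again 3 adjusted over the list alone. That list was higher on balance with a median of 0.28 and an adjusted p of 0.0145, and the adjusted p = 0.551 with an estimated correlation. Its difference from the control lines at 8 h was not called (median -0.02, adjusted p = 0.154). Among 17 auxin response factors, ARF10 and ARF2 rose and ARF17 fell, and adjusted over the list alone the counts were again 2 and 1. Without CRL1 lines 2 and 3 the adjusted p was 0.189 and 0.174 for ARF10 and 0.12 and 0.167 for ARF2. Without any 1 of the CRL1 lines it was 0.0689 to 0.238 for ARF17 and 0.111 to 0.173 for GH3.4, and for GH3.4 it was 0.0516 with no filter and 0.0537 with array weights. The brassinosteroid-inactivating CYP734A6 rose by 2.33 ± 0.3 and the abscisic acid hydroxylase CYP707A5 by 3.23 ± 0.32. Over the 28 measured cytochrome P450 enzymes 3 rose and 1 fell.

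Wall and replication genes were the other lists called at 8 h. Of 30 expansins and wall-remodelling enzymes 7 rose and 4 fell, and 10 and 6 adjusted over the list alone. Without CRL1 line 2 the counts were 5 and 1. The risers included Cel9A, EXPB18 and EXPB6, the last by 1.74 ± 0.16, and the list was higher on balance with a median of 0.18 and an adjusted p of 0.00626. The adjusted p = 0.551 with an estimated correlation. Of 35 histone and DNA replication genes, 5 rose and none fell, with 6 rising adjusted over the list alone. Without CRL1 lines 1, 2 and 3 the count of 5 was 1, 1 and 3. RFC1, a subunit of the clamp loader, rose by 1.37 ± 0.14 and the replicative helicase subunit MCM5 by 1.49 ± 0.27, and the list had a median of 0.32 and an adjusted p of 0.00014. The adjusted p = 0.82 with an estimated correlation. For the replication list the difference from the control lines at 8 h was not called (adjusted p = 0.0809). Without CRL1 line 1 the adjusted p of the wall list was 0.0865, without CRL1 line 2 that of the replication list was 0.116, and without these lines MCM5 stood at 0.0559 and 0.07. In total 1140 probe sets were higher and 955 lower, or 1737 and 1906 with line as a block. The total was 831, 492 and 954 without CRL1 lines 1, 2 and 3. Of the 136 probe sets higher at 4 h, 129 were also higher at 8 h, against 4.72 for independent lists. Both came from the same lines and 1 estimate of the spread, so they were not independent and an overlap above 4.72 shows little.

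Control lines show what dexamethasone did without the CRL1 transgene. No single transcript passed the test in them. QHB had a log2 change of 0.12 at 4 h and 0.03 at 8 h, CBL4 of 0.13 and -0.42, and GH3-8 of 0.82 and 0.87, none of which was called. The 136 probe sets called higher at 4 h in the CRL1 lines had a median change of 1.62 there and of 0.12 in the control lines, and the 1140 called higher at 8 h had medians of 1.23 and 0.03. The 7 called lower at 4 h had a median of -1.19 in the CRL1 lines and were lower in both control lines too, with a median of -0.57.

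In the control lines limma called 0 of 32836 probe sets at 4 h and 0 at 8 h. At an unadjusted p under 0.05 there were 781 and 838, fewer than the 1642 that 0.05 of the tests would give. The spread in that fit includes the difference between the control lines, which a change within lines does not hold. With line as a block the calls were also 0, with 1563 and 1429 at an unadjusted p under 0.05. The 0 calls alone do not show that dexamethasone had no effect in these lines. Without control line 2, 4 were called at 4 h. In simulated arrays with the same number of lines, 64% of changes of 2 on the log2 scale were recovered at 4 h and 69% at 8 h. Of changes of 1 only 28% and 35% were recovered. Those arrays were drawn without differences between lines, so these shares do not measure the power in the real control lines. Some lists shifted by small amounts: crown root regulators and Aux/IAA proteins were lower at 4 h, with medians of -0.36 and -0.2 and an adjusted p of 0.0277 each. The adjusted p = 0.507 and 0.767 with an estimated correlation. At 8 h expansins and wall-remodelling enzymes (median -0.12, adjusted p = 0.0248) and root tissue genes (median -0.43, adjusted p = 0.00589) were lower, and histone and replication genes (median 0.11, adjusted p = 0.00589) were higher. The adjusted p = 0.388, 0.719 and 0.719 with an estimated correlation, in that order. Each of these calls rested on 1 or both control lines: without control line 1 the adjusted p was 0.137 for both lists at 4 h, 0.437 for wall enzymes and 0.774 for replication genes. Without control line 2 it was 0.0571 for crown root regulators, 0.0552 for Aux/IAA proteins and 0.552 for root tissue genes. With line as a block, cyclins were also higher and cellulose synthases lower at 8 h (adjusted p = 0.0317 and 0.0452).

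Subtracting the control lines' mean response tested whether the dexamethasone response differed between the CRL1 lines and the control lines. That mean joins the untransformed line, which lacks the vector, with the empty-vector line. An effect of the vector itself would therefore be removed only in part. Averaged over both times, EXPB18 was higher by 4.4 ± 0.78 (adjusted p = 0.0119, limma), CBL4 by 3.65 ± 0.39 (adjusted p = 0.000151) and QHB by 3.32 ± 0.5 (adjusted p = 0.00319) on the log2 scale. The difference was 3.26 ± 0.49 for HMG1, 2.87 ± 0.36 for CYP734A4, 2.14 ± 0.46 for GH3-8, 1.94 ± 0.36 for CYP707A5 and 1.88 ± 0.32 for IMCEL2. For proT and Roc4 it was 1.82 ± 0.2 and 1.82 ± 0.35. Only 2 named genes met the rule in the other direction: EXPA6, with -1.25 ± 0.24, and ER2, of the ERECTA receptor kinase family, with -0.94 ± 0.18. For EXPB18 and HMG1 5 of the 8 group means were under the array median, and the difference was 6.42 and 3.47 with no offset and 2.44 and 2.49 with an offset at the median. For CBL4 1 of the 8 was, and the difference was 3.8 with no offset and 2.99 with an offset at the median. EXPB18 and Cel9A were also called higher at 8 h alone. Of their 4 groups only the dexamethasone-treated CRL1 lines had a mean above the array median, and the control lines' mean for EXPB18 went from 9.5 after mock treatment to 1.15 after dexamethasone. The size of these differences is therefore not settled: it was 10.49 for EXPB18 and 7.9 for Cel9A with no offset, and 4.32 and 5.05 with an offset at the median. At 8 h the difference was -1.82 ± 0.4 for Hox21, -1.69 ± 0.3 for NEK2, -1.6 ± 0.26 for ER2 and -1.36 ± 0.25 for the cellulose synthase-like CSLA9.

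Leaving out 1 line ended many of these calls. For the mean of both times CBL4, CYP734A4 and proT kept theirs without each line. Of the 12 named genes 8 lost it without control line 1 (0.0553 to 0.24), 7 without control line 2 (0.0657 to 0.165), 6 and 7 without CRL1 lines 1 and 2 (0.0599 to 0.261 and 0.0579 to 0.262), and EXPA6 and ER2 without CRL1 line 3 (0.102 and 0.105). At 8 h alone EXPB18 lost its call without control lines 1 and 2 (0.0515 and 0.115), and Hox21, NEK2 and CSLA9 lost theirs without either control line and without CRL1 lines 2 and 3 (0.0611 to 0.336). CSLA9 also lost it without CRL1 line 1 (0.168). ER2 lost it without control line 2 (0.0699) and CRL1 lines 2 and 3 (0.0572 and 0.0503). Cel9A kept its call at 8 h without each line, but under the stricter filter on dim probe sets Cel9A (0.56) and EXPB18 (0.157) lost theirs at 8 h, and EXPB18 (0.278) and HMG1 (0.0506) for the mean. With array weights Roc4 (0.072) and EXPA6 (0.0875) lost theirs for the mean, and Hox21, NEK2 and CSLA9 (0.103 to 0.368) at 8 h. With only the groups compared these 3 and ER2 did so at 8 h (0.0584 to 0.189), and Hox21 also with no offset (0.055) and no filter (0.0628).

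Expansins and wall-remodelling enzymes were the only list called in this difference, at either time and for the mean. For the mean of both times 5 of 30 were higher and 1 lower, with 7 and 2 adjusted over the list alone, a median of 0.27 and an adjusted p of 3.44e-05, and with an estimated correlation the adjusted p = 0.0439. The total of 6 called members was 2 without control line 1, without control line 2 and without CRL1 line 2. At 4 h and 8 h alone the adjusted p was 0.00558 and 0.000116, and with an estimated correlation the adjusted p = 0.116 and 0.0929. Without CRL1 line 1 the list was not called at 4 h (adjusted p = 0.116). The same list was lower in the control lines at 8 h, as given above, which enters this difference. Of the crown root regulators QHB was called, and hox14 (3.1 ± 0.91, with 6 of 8 group means under the array median), IAA23 (0.98 ± 0.25) and RR2 (-0.86 ± 0.29) passed only with line as a block, at adjusted p = 0.0277, 0.0442 and 0.0178. Adjusted over the list alone 3 were higher and 1 lower. WOX11 stood at -0.8 ± 0.55, RR1 at 0.61 ± 0.57, IAA13 at -0.25 ± 0.23, SHR1 at -0.19 ± 0.2, CKX4 at -0.18 ± 0.42 and SCR1 at -0.16 ± 0.26. The last 2 changed sign without 1 line: CKX4 stood at 0.25 without control line 2 and 0.03 without CRL1 line 2, and SCR1 at 0.09 without control line 1 and 0.04 without CRL1 line 1. QHB lost its call without CRL1 lines 1 and 2 (adjusted p = 0.0599 and 0.0793).

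Over all probe sets 245 were higher and 35 lower for the mean of both times, 187 and 46 at 8 h, and 3 and 0 at 4 h. With line as a block these were 504 and 149, 495 and 222, and 3 and 0, with 2 of the 3 shared. The 3 at 4 h, named after their values were seen, were 1 probe set not listed with a gene in the annotation used, with a difference of 8.11 ± 0.88 (8.63 with no offset and 6.47 with an offset at the median, with 2 of 4 group means under the array median), and the probe sets of LOC4332081 (2.64 ± 0.38) and LOC4332560 (2.33 ± 0.33). LOC4332081 was the one lost with the block (adjusted p = 0.0545). Without control line 1 and without each CRL1 line both genes lost their calls (0.129 to 0.777), as did LOC4332560 and LOC4332081 under quantile normalization (0.0692 and 0.0739) and with only the groups compared (0.154 and 0.331), and the unlisted probe set did so without CRL1 lines 1 and 2 (0.336 and 0.215). The total for the mean was 84 without control line 1 and 142 without control line 2, and 110 and 87 without CRL1 lines 1 and 2. At 8 h it was 66 and 62 without either control line and 101 and 81 without CRL1 lines 1 and 2; at 4 h it was 1 and 6 without control lines 1 and 2, and 0, 0 and 6 without CRL1 lines 1, 2 and 3. In those limma fits with 0 calls 770 and 622 probe sets had an unadjusted p under 0.05.

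Whether the response of the CRL1 lines itself changed between 4 h and 8 h was tested for each transcript. Cel9A and MYBS2, a MYB factor of sugar response, were the only called probe sets. The response of Cel9A was larger at 8 h by 7.04 ± 0.63 (adjusted p = 0.000214, limma) and that of MYBS2 by 1.53 ± 0.17 (adjusted p = 0.00278), with another probe set of MYBS2 going the other way. Of the 4 group means of Cel9A 3 were under the array median, and its change was 7.95 with no offset and 5.13 with an offset at the median. The signal of MYBS2 after dexamethasone was 1010 ± 111.0 at 4 h and 2130 ± 255.0 at 8 h (SD, n = 3). Histone and DNA replication genes had a larger response at 8 h as a list (median 0.34, adjusted p = 1.79e-07), and with an estimated correlation the adjusted p = 0.657. None of its members was called over all genes and 1 was higher adjusted over the list alone. The control lines did not enter this comparison. In them the replication list was higher at 8 h (adjusted p = 0.00589, as given above) and not called at 4 h (0.416). The count of 2 became 58 with line as a block, where auxin response genes and wall enzymes were also higher and bHLH factors and shoot meristem genes lower (adjusted p = 0.034, 0.0329, 0.0182 and 0.0348). Without CRL1 line 2 or 3 the count was 1. Cel9A lost its call without CRL1 line 2 (adjusted p = 0.064) and under the stricter filter on dim probe sets (0.841), and MYBS2 without each of CRL1 lines 1, 2 and 3 (0.102, 0.0755 and 0.255).

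Mock-treated CRL1 lines were set against mock-treated control lines to see how the lines differed before induction. The groups differed at 1 probe set, that of LOC4340325, which is named here after its value was seen. It was higher in the CRL1 lines by 5.01 ± 0.33 on the log2 scale (adjusted p = 1.8e-06, limma with line as a random block), with mean signals of 306 and 318 at 4 h and 8 h against 11 and 6.4 in the control lines, which were under the array median. The difference was 5.32 with no offset and 4.0 with an offset at the median. Defence proteins were lower on balance (14 measured, median -0.77, adjusted p = 0.00128), as were root tissue genes (15 measured, median -0.78, adjusted p = 6.5e-05), cytochrome P450 enzymes (28 measured, median -0.46, adjusted p = 6.92e-05), NAC factors (adjusted p = 0.0292) and cytokinin genes (adjusted p = 0.0414). For each of these 5 lists the adjusted p = 0.369 with an estimated correlation. Ribosomal proteins (26 measured, median 0.21, adjusted p = 4.3e-10), cellulose synthases (adjusted p = 0.00232) and histone and replication genes (adjusted p = 0.00155) were higher. The adjusted p = 0.369, 0.369 and 0.484 with an estimated correlation, in that order. No member of these lists was called over all genes, and adjusted over the list alone 2 NAC factors were lower and no member of the other 7 lists was called. Without control line 1 the adjusted p was 0.169 for defence proteins, 0.685 for cytochrome P450 enzymes, 0.419 for NAC factors and cellulose synthases and 0.117 for cytokinin genes. Without control line 2 it was 0.106 for histone and replication genes and cytokinin genes and 0.0642 for NAC factors, and without CRL1 lines 2 and 3 it was 0.0817 and 0.0939 for cytokinin genes. Root tissue genes and ribosomal proteins were called without each line.

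The 2 control lines were not alike. The first principal component, with 28.7% of the variance, set all 4 arrays of the untransformed control line (scores of -112.2 to -67.4) apart from the other 16 (-0.3 to 54.9). Without the empty-vector line the comparison called 3936 probe sets, and without the untransformed line it called 7. The mean log2 ratio of 3' to 5' signal over 7 pairs of rice control probe sets ran from 0.67 to 1.89 on the arrays of the untransformed line and from 0.68 to 1.78 on the others. Without CRL1 line 3 the count was 3, and with no replicate block it was 1.

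**Figure D2:**
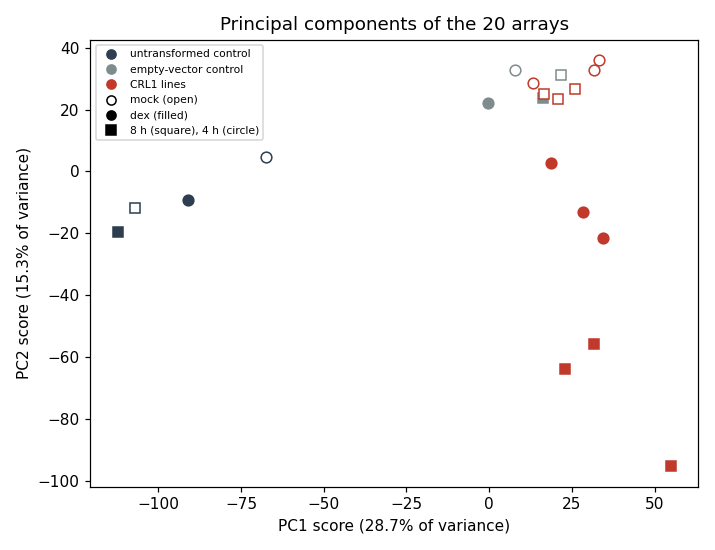
Scores of the 20 arrays on the first and second principal components of the log2 signals, with axes in score units and 28.7% and 15.3% of the variance. Open symbols are mock and filled ones dexamethasone, circles are 4 h and squares 8 h, and colour gives the kind of line. The 4 arrays of the untransformed control line lie at -67.4 or below on the first component, and dexamethasone-treated CRL1 arrays at 8 h lie lowest on the second.

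Time in liquid medium differed between the collections, which mock-treated arrays of all 5 lines measured. Time of day may have differed too, but the labels give no clock time. BBD1, a nuclease gene, was higher at 8 h than at 4 h by 1.34 ± 0.21 on the log2 scale (adjusted p = 0.0291, limma). The kinase gene CIPK7 fell by 1.12 ± 0.16 and MRS2-A, of a magnesium transporter family, by 0.84 ± 0.13, each with an adjusted p of 0.0291 and in all 5 lines, although another probe set of CIPK7 went the other way. Of 6 clock genes none passed over all genes, and adjusted over the list alone 2 were higher (PRR1 and GI) and 3 lower (LHY, PRR95 and PRR73). LHY, a morning-phased clock gene, had a log2 change of -1.6 ± 0.32 and PRR95 of -0.53 ± 0.18, and both passed with line as a block (adjusted p = 0.0196 and 0.0487). GI stood at 0.59 ± 0.18, PRR1 at 0.52 ± 0.12, PRR73 at -0.25 ± 0.08 and PRR37 at 0.05 ± 0.22. Heat shock proteins were lower on balance at 8 h (21 measured, median -0.28, adjusted p = 5.08e-05), and with an estimated correlation the adjusted p = 0.0121. Ribosomal proteins were higher (median 0.11, adjusted p = 0.000179), and with an estimated correlation the adjusted p = 0.763. Limma called 5 probe sets higher and 8 lower, 26 and 51 with line as a block. The total was 0 without any 1 of CRL1 lines 1, 2 and 3, where limma left 1296, 1404 and 1030 at an unadjusted p under 0.05, and 75 and 34 without control lines 1 and 2. The adjusted p of BBD1, CIPK7 and MRS2-A without 1 CRL1 line lay between 0.31 and 0.854, and with only the groups compared it was 0.122 for BBD1 and MRS2-A. Ribosomal proteins were not called without CRL1 line 3 (adjusted p = 0.138). Cytokinin genes were also lower with line as a block (adjusted p = 0.0279).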

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

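The tests of RNA degradation and of dexamethasone or the vector's receptor were chosen after their results could be seen in part, and the other tests of the patterns weighed here were set out beforehand. The splits within lines for time after mock treatment, given with the other observations, were also chosen afterwards. Differences between the dexamethasone responses of the CRL1 lines and the control lines were tested as such and called 3 probe sets at 4 h, 233 at 8 h and 280 for the mean of both times. For the mean, 46 called probe sets belonged to a named gene. Those picked by the rule for the largest changes were EXPB18 (4.4 on the log2 scale), CBL4 (3.65), QHB (3.32), HMG1 (3.26), CYP734A4 (2.87), GH3-8 (2.14), CYP707A5 (1.94), IMCEL2 (1.88), proT (1.82), Roc4 (1.82), EXPA6 (-1.25) and ER2 (-0.94). CBL4, CYP734A4 and proT kept their calls without each line, and the other 9 lost theirs without at least 1 CRL1 line. The response of the CRL1 lines differed between 4 h and 8 h for 2 probe sets, Cel9A (7.04) and MYBS2 (1.53). The sizes for EXPB18, HMG1 and Cel9A depend on the offset, since most of their group means were under the array median. For CBL4 1 of 8 was, and its difference was 3.8 with no offset and 2.99 with an offset at the median. Groups held 2 or 3 arrays, so no sample was tested as lying far from its group.

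The rise of transcripts in the CRL1 lines could come from dexamethasone itself or from the vector's receptor. In the empty-vector line, the probe sets called higher in the CRL1 lines changed by a median of 15.9% of the CRL1 lines' median at 4 h and 2% at 8 h. This argues against either as the whole cause, since a median of at least 50% was needed. The probe sets were chosen for their rise in the CRL1 lines, which lowers the share, and the empty-vector line gave 1 array per group. At 4 h 100 of the 136 rose in the empty-vector line (median 0.26) and 69 in the untransformed line (median 0.01). A part at 4 h stays open, and the 7 probe sets lower at 4 h had medians of -0.54 and -0.55 in the control lines. That the 3 CRL1 lines share a biological response to CRL1 is a hypothesis the design names. Of 10 splits of the 6 arrays, the real one gave 143 calls at 4 h and the highest other 0; at 8 h these were 2095 and 1. For the mean difference the real split of the 5 lines gave 280 and the highest other 16. With 10 splits no share under 0.05 is possible: 1 of 10 reached the real count in each case. Splits that also part all 3 lines' pairs gave 0 calls at both times.

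More probe sets were called at 8 h than at 4 h, although the change itself was called for 2. A single CRL1 line as the source would bring the counts together when it is left out. The lowest ratio of calls at 8 h to calls at 4 h without 1 line was 14.2, so the higher count at 8 h remained. A change in 1 line alone widens the spread and is seldom called, so this test could hardly have come out otherwise. The count at 8 h itself fell from 2095 to 492 without CRL1 line 2. The 136 probe sets called higher at 4 h had a median log2 change of 2.05 at 8 h, and 101 of them changed more at 8 h. For the change between times the real split gave 2 calls and the highest other 0, with 1 of 10 splits as large, too few for a share under 0.05.

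The untransformed control line stood apart from the other 4 lines. Its arrays had median signals of 12.5, 13.3, 15.5 and 15.0, and no other array was above 12.5. A difference in array brightness would close after quantile normalization, but 99.4% of the gap on the first component was left. That step evens out only the distribution of signals, so it cannot speak to array differences particular to some probe sets. RNA degradation would raise the 3' to 5' ratio on all 4 arrays, and 2 of the 4 lay at or under the median of the other 16 (1.4), with 1 above all others. Both are argued against as the whole cause; transformation and regeneration, a separate seed lot or a handling difference were not tested and are confounded with this single line. Other splits of the 5 lines gave up to 4 calls for mock-treated lines against 1 for the real one, and 4 of 10 splits gave at least as many, too few splits for a share under 0.05.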

How the results depend on the processing

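Of 146 recomputed counts of calls 86 stayed within 1.5 times of the reported one and 60 moved, and the cause was not tested for those that moved unless stated. For named genes and called lists 1794 of 2166 recomputed results kept their direction and side of the threshold, 346 lost the call, 21 gained one and 5 changed sign. Of the named genes with the largest changes, some also lost the call under a setting that kept all lines: 2 of 10 in the CRL1 lines at 4 h, 6 of 20 at 8 h, 8 of 10 for the difference at 8 h, 4 of 12 for its mean, 1 of 2 for the change between times and 2 of 3 for time after mock treatment. The pairing by line came from the labels, and line as a fixed replicate block took up differences between lines. With the block the CRL1 lines had 354 calls at 4 h and 3643 at 8 h, the difference of responses 717 at 8 h and 653 for the mean of both times, the change between times 58, and time after mock treatment 77. Lists called over 9 comparisons were 25 with the block against 16 without it. Among the results printed, the block changed no call other than those given beside them. With line as a random block the counts were 300, 3363, 615, 597, 32 and 47 in the same order, and 9 for the difference at 4 h. Array weights gave 414 for the CRL1 lines at 4 h, 5, 58 and 181 for the difference at 4 h, at 8 h and for the mean, and 12 for the change between times. With only the groups compared in the fit, and so fewer arrays to estimate the spread, there were 231 calls for the CRL1 lines at 4 h, 1 and 75 for the difference at 4 h and 8 h, and 4 for time. For the mean difference that fit holds all arrays and is the reported one. Quantile normalization gave 1 for the difference at 4 h. An offset at the median gave 12 and the stricter filter, with fewer probe sets tested, gave 1 for the change between times. With an estimated correlation 2 of the 24 called lists were left. Leaving out each line in turn gave 12 to 224 calls for the CRL1 lines at 4 h and 492 to 2736 at 8 h, 0 to 4 for the control lines at 4 h, and 0 at 8 h with each line left out (limma, with 686 to 1305 at an unadjusted p under 0.05). It gave 0 to 6, 62 to 171 and 84 to 212 for the difference at 4 h, at 8 h and for the mean, 1 to 3 for the change between times, 1 to 3936 for mock-treated lines, 0 to 75 for time and 22 to 38 called lists. Fewer lines also mean fewer arrays, and a lone control array is assumed there to vary like the other groups. SCR1 ran from -0.4 to 0.09 for the mean difference without 1 line, with 0.04 without CRL1 line 1, and CKX4 from -0.62 to 0.25, with 0.03 without CRL1 line 2. PRR37 ran from 0 to 0.09 for time. Signals near background limit the folds of genes silent after mock treatment: Cel9A changed at 8 h by 7.62 with no offset and 5.05 with an offset at the median, and EXPB18 by 7.45 and 3.62.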

Other observations

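The test of time after mock treatment against splits within lines was chosen after the count for splits across lines was seen. Of 21 measured heat shock genes 4 rose and 1 fell in the CRL1 lines at 8 h, 5 and 2 adjusted over the list alone, and the list was not called (adjusted p = 0.134). The total of 5 was 3, 2 and 2 without CRL1 lines 1, 2 and 3. HSP26.2 rose by 2.29 ± 0.31, HSP24.1 by 1.86 ± 0.27, HSP17.4 by 1.17 ± 0.27 and HSP18.8 by 0.84 ± 0.21 on the log2 scale. HSP17.4 lost its call without CRL1 lines 2 and 3 (adjusted p = 0.198 and 0.169) and HSP18.8 without any 1 of the CRL1 lines (0.0597 to 0.208). Among 40 cyclin and cyclin-dependent kinase genes 4 rose and 3 fell, 5 and 4 adjusted over the list alone, with CYCD5-2 at 0.92 ± 0.2 and CYCD3-2 at -0.77 ± 0.15. The total of 7 was 2, 2 and 1 without CRL1 lines 1, 2 and 3. Without CRL1 lines 2 and 3 the adjusted p of CYCD5-2 was 0.253 and 0.138, and without CRL1 lines 1 and 3 that of CYCD3-2 was 0.0685 and 0.126; with only the groups compared these were 0.0684 and 0.0583. Of 47 homeobox genes 6 rose and 5 fell, 7 and 6 adjusted over the list alone, and without CRL1 line 2 the counts were 4 and 1. Hox13 rose by 1.76 ± 0.21 and Roc4 by 2.41 ± 0.32, and both kept their calls without each line. The gibberellin synthesis gene GA20OX3 rose by 1.33 ± 0.14, 1 of 14 measured gibberellin genes and also 1 adjusted over the list alone. Of 29 cytokinin genes 2 rose and 3 fell, with the counts the same adjusted over the list alone, including the oxidase gene CKX5 at 2.66 ± 0.66 and RR6 at -1.23 ± 0.28. Without any 1 of the CRL1 lines at most 1 cytokinin gene was called, and CKX5 and RR6 lost their calls (adjusted p of 0.0831 to 0.348 and of 0.0595 to 0.322).

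Markers of other tissues were not called as lists in the CRL1 lines at 8 h: photosynthetic leaf genes had a median of -0.21 (adjusted p = 0.763), vascular genes of -0.32 (adjusted p = 0.37), shoot meristem genes of -0.36 (adjusted p = 0.113) and root tissue genes of -0.08 (adjusted p = 0.846). Of single members 1 vascular gene rose and 2 fell, 2 shoot meristem genes fell and 1 root tissue gene rose. Without CRL1 lines 1 and 2 the shoot meristem and root tissue calls were lost and 1 vascular call was left. The adjusted p at 8 h was 0.977 for glutathione S-transferases, 0.927 for ribosomal proteins, 0.859 for WRKY factors, 0.846 for NAC factors and clock genes, 0.949 for AP2/ERF factors and cyclins, 0.778 for gibberellin genes, 0.79 for homeobox genes, 0.763 for defence proteins, 0.427 for bHLH factors, 0.357 for auxin response factors, 0.134 for cellulose synthases, 0.123 for cytochrome P450 enzymes and 0.846 for cytokinin genes. PIN5a, of the auxin transport genes, fell by 1.46 ± 0.32, with an adjusted p of 0.0579 and 0.223 without CRL1 lines 1 and 2.

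Chosen after their values were seen, 1 probe set not listed with a gene in the annotation used and the probe set of LOC4330584 were called higher in the CRL1 lines at both times. Their mock signals were under the array median, so the size depended on the offset: at 8 h it was 9.05 and 9.23 with no offset and 6.89 and 7.48 with an offset at the median, and at 4 h 7.09 and 8.76 against 5.71 and 5.07. Whether the unlisted probe set measures the CRL1 transgene is not known. LOC4330584 has no other name in the tables used, and at 4 h its call was lost without CRL1 lines 1 and 2 (adjusted p = 0.184 and 0.28) and with only the groups compared (0.0606). At 8 h mean signals after mock treatment and dexamethasone were 4.07 ± 2.57 and 2000 ± 846 for the unlisted probe set (SD, n = 3). For LOC4330584 they were 5.23 ± 1.76 and 3280 ± 1610 at 8 h. At 4 h those of LOC4330584 were 1.17 ± 1.08 and 1040 ± 1000, so the lines differed widely.

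For time after mock treatment, the 10 arrays are paired by line, and exchanging times within lines gives 16 splits. Under a model with line kind and time as separate terms the real split gave 21 calls and the highest other 0, so 1 of 16 splits gave as many, too few splits for a share under 0.05. Among 100 drawn splits (of 126 possible) most also moved both arrays of a line to the same side, so that differences between lines entered them; the highest other gave 5. In the reported limma model, which gave 13 calls, the count was 0 without any 1 of the CRL1 lines, with 1296, 1404 and 1030 probe sets at an unadjusted p under 0.05.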
